A study of Mus musculus with 16 samples.

How the data were processed

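Single-cell RNA sequencing of CD45-positive, 7AAD-negative lung cells covered 16 libraries of 6 C57BL/6 mice, with 2 mice per group. Per the labels' protocols, lungs were perfused with PBS and digested with collagenase I, cells were sorted on a FACS Aria, and inDrops libraries were sequenced on a NextSeq. Per the labels, the healthy mice were male and about 14 weeks old, and gave 5 libraries. The tumour-bearing mice were female and received KP1.9 cells, also per the labels. From week 4, for 2 weeks, they received, per the labels, 14 injections of vehicle (5 libraries) or BLZ945 (6 libraries). The mouse was the replicate, and the libraries of a mouse were summed.

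The deposited count matrices hold UMI counts per cell barcode and gene for 40930 genes. The authors made them with the inDrops pipeline, per the file headers of the deposited settings. Reads were demultiplexed with bcl2fastq 2.17.1.14 and aligned by bowtie to transcripts of mouse GRCm38, release 91 (m = 200, n = 1, l = 12), with samtools 1.3.1, per the same headers. Reads with over 10 alignments and UMIs that fit more than 1 gene were ignored, and alignments had to lie within 600 nt of the transcript end with at least 15 nt outside the poly-A tail, also per these headers. Tumour libraries were inDrops version 3 with 54 nt reads (bowtie e = 110), and healthy libraries version 2 with 35 or 36 nt reads (e = 70), per the same settings. The deposited cell table gives the authors' percent of mitochondrial UMIs per cell and a doublet score. How the percent and the score were made is not given in the sources used here. The values show at least 600 UMIs and under 15% mitochondrial UMIs per cell in that table. Only the mitochondrial percent was used here, and the score served to count cells without one (1554).

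The deposited table holds 27563 cells, of which the authors gave 25039 a cell type. All named cells had at least 1000 UMIs. The 2524 without a name comprised, per the deposited table, 881 marked as doublets, 12 as red blood cells, 24 as Krt8-high, 1554 under 1000 UMIs and 53 others, and were left out of the tests. Cell types are the authors' 8 major types and 28 finer subsets. The named cells of a mouse held 6708836 and 6156065 UMIs in healthy mice, 16061385 and 8923867 with vehicle, and 7933696 and 19444277 with BLZ945. Median genes per cell were 791 and 709, 947.5 and 901, and 961 and 1023.

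Before the data were examined, the tests, the gene panel, 22 gene lists, the threshold of 0.05 and most alternatives were fixed. Numbers of cells per type and mouse were tested with edgeR 4.0.16 (quasi-likelihood), offset by all named cells of the mouse, with Benjamini-Hochberg adjustment over the types. Gene tests used UMI counts summed per mouse and type, for types with at least 20 cells in each mouse, with TMM factors, filterByExpr at a minimum count of 10, a robust edgeR quasi-likelihood fit and Benjamini-Hochberg adjustment over the genes of a type. Lists with at least 5 tested members were tested by camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over lists and types. The camera test with an estimated correlation is given beside it. With few residual degrees of freedom in 4 mice, it passed none of the 61 and 27 list calls made with the preset value. It therefore cannot tell these lists apart. Some lists share members, such as Psmb9 in the IFN-gamma and MHC class I lists, so their results are not independent. The p with the preset value rests on the spread over genes and hardly on that between mice. With 2 against 2 mice an exact permutation test cannot give a p under the threshold. R 4.3.3 was used. CPM values scale the counts to the UMIs of the type in the mouse.

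Genes were named by a rule fixed in advance. It took the 3 largest rises and 3 largest falls per type with at least 10 calls, among genes past the threshold whose groups did not overlap and with a mean of at least 50 CPM in the higher group. Immunoglobulin, haemoglobin, mitochondrial and ribosomal genes and markers of other types were left out. In vehicle against healthy mice, this part covered the 4 types with most cells. The rule added the panel, up to 4 members with the smallest p of each list past the threshold, and 3 genes as a check of the sex labels. It named 531 pairs of gene and type (334 and 197 in the 2 comparisons). Of these, 238 (143 and 95) were kept for the text after their values were seen, and the examples printed come mostly from genes whose call stood without each mouse in turn. They therefore appear steadier than the full set. Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio has a 95% counting interval. This interval treats the pooled counts as independent and leaves out the spread between mice and between cells. Shares of cells with a UMI are given also with each cell thinned to 500 or 1000 UMIs.

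The alternatives were RLE factors, DESeq2 1.42.0, no filter beyond 1 UMI, a minimum count of 30, all 6 mice in 1 fit, each mouse left out, the mouse number as a block, TMM factors on cell numbers, no neutrophils, only the largest library of each mouse, and for lists an estimated correlation or fry. A planned minimum of 1000 UMIs per cell removed no named cell, and a minimum of 1500 was added after the data were seen. Where a group keeps 1 mouse, that mouse is assumed to vary like the other group. Such a fit holds no spread within that group, so a gene that passes only there is not taken as a call.

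The tests were tested on simulated data with 200 changed genes per type. For BLZ945 against vehicle, changes of 1.5-fold, 2-fold and 4-fold were recovered for 20.9%, 58.2% and 87.9% of genes in neutrophils (15971 genes) and for 5.97%, 31.3% and 81.8% in T cells (7084 genes). Among all simulated calls of a type, 4.82% to 9% were false. A list raised 1.5-fold was recovered in 20 of 20 simulations in each type tried. The gene and list simulations drew each gene independently, with 1 common dispersion per type. They therefore do not show the recovery or false calls to be met with correlated list members or gene-specific spread. A 3-fold change of a cell type was recovered in 71.5% (major) and 26% (finer) of 200 simulations for BLZ945 against vehicle, and in 34% and 9.5% for vehicle against healthy. That simulation first changed any type, and called others through the shared total. It was restricted afterwards to changes in types under 20% of cells. Unchanged major types were still called in 6.4% of tests for BLZ945 against vehicle and 3.6% for vehicle against healthy, and finer ones in 0.261% and 0.455%. Types with few cells were left out, which kept 6 major types and 24 or 23 finer ones. It therefore does not cover sparse types such as basophils in either comparison, N2 with BLZ945 or pDC against healthy mice.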

Results

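CD45-positive lung cells of 6 mice were profiled by single-cell RNA sequencing: 2 healthy mice, 2 mice bearing KP1.9 lung tumours given vehicle, and 2 tumour-bearing mice given BLZ945, an inhibitor of the receptor kinase CSF1R. The authors named 25039 cells: 2948 and 3385 in the healthy mice, 5440 and 3412 with vehicle, and 3019 and 6835 with BLZ945. Median depth per named cell was 1998.5 and 1673 UMIs in the healthy mice, 2242.5 and 2064.5 with vehicle, and 2208 and 2349 with BLZ945. Values below are means with the SD over 2 mice, and log2 fold changes carry their standard error.

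With BLZ945, the shares of 2 macrophage subsets, Mac1 and Mac3, fell, and those of the monocyte subsets Mono2, Mono3 and MonoDC rose. The authors' Mac1 subset made up 8.14 ± 0.895% of cells with vehicle and 1.87 ± 0.583% with BLZ945 (log2 fold change -2.11 ± 0.56, adjusted p = 0.00309). Mac3 fell from 0.853 ± 0.0368% to 0.114 ± 0.067% (log2 fold change -2.74 ± 0.70, adjusted p = 0.0024). Mono2 counted 0 cells with vehicle, a share under 0.0339%, and 72 cells with BLZ945, at least 21.6-fold higher against a floor of 3 cells over the group (adjusted p = 2.05e-06). Mono3 rose from 0.587 ± 0.209% to 2.18 ± 0.575% (log2 fold change 1.85 ± 0.59, adjusted p = 0.00868), and MonoDC from 0.0827 ± 0.117% to 0.514 ± 0.023% (log2 fold change 2.39 ± 0.75, adjusted p = 0.00868). Monocytes and macrophages together were 14.2 ± 2.66% and 11.2 ± 0.589%, which did not pass (log2 fold change -0.34 ± 0.20, adjusted p = 0.246). Neutrophils, the largest type, were 68.3 ± 1.26% with vehicle and 54.4 ± 0.114% with BLZ945, which did not pass by edgeR either (log2 fold change -0.33 ± 0.13, adjusted p = 0.14). Shares of a mouse add up to a whole, so a smaller neutrophil share alone raises the shares of other types.

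Other subsets moved as well. Plasmacytoid dendritic cells (pDC), the main producers of type I interferon, numbered 59 with BLZ945 and 1 with vehicle, a ratio of 53.0 (95% counting interval 9.15 to 2128, adjusted p = 4e-05). DC1, the cross-presenting dendritic cells, rose from 0.358 ± 0.0917% to 1.1 ± 0.00298% (log2 fold change 1.58 ± 0.62, adjusted p = 0.029). NK cells rose from 0.834 ± 0.478% to 2.98 ± 0.558% (log2 fold change 1.86 ± 0.58, adjusted p = 0.00868) and CD4 T cells from 1.57 ± 0.476% to 4.67 ± 0.184% (log2 fold change 1.58 ± 0.56, adjusted p = 0.0173). Basophils numbered 27 with BLZ945 and 3 with vehicle, a ratio of 8.09 (interval 2.49 to 41.6, adjusted p = 0.00868). Among neutrophil subsets, N5 rose from 1.67 ± 0.367% to 4.85 ± 0.487% (log2 fold change 1.54 ± 0.56, adjusted p = 0.0189). N6 fell from 7.96 ± 0.682% to 2.71 ± 0.105% (log2 fold change -1.55 ± 0.55, adjusted p = 0.0173), and N3 from 5.9 ± 3.49% to 2.39 ± 0.55% (log2 fold change -1.31 ± 0.55, adjusted p = 0.0421). N2 numbered 19 with BLZ945 and 1 with vehicle, a ratio of 17.1 (interval 2.71 to 709.2, adjusted p = 0.00662). Regulatory T cells (log2 fold change 1.25 ± 0.59, adjusted p = 0.0653), DC3, the mature dendritic cells (log2 fold change 0.62 ± 0.57, adjusted p = 0.395), and the largest neutrophil subset, N4 (log2 fold change 0.12 ± 0.53, adjusted p = 0.874), did not pass.

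Of 28 subsets, 10 rose, 4 fell and 14 did not pass, while 18 had an unadjusted p under 0.05 by edgeR. With neutrophils left out of the cell numbers, which leaves their subsets untested, 4 subsets passed. At the level of major types, 0 of 8 passed by edgeR, the only tool run on cell numbers, and 3 had an unadjusted p under 0.05: B cells (log2 fold change 1.21 ± 0.30, adjusted p = 0.0715), basophils (log2 fold change 2.96 ± 0.61, adjusted p = 0.0715) and NK cells (log2 fold change 1.87 ± 0.50, adjusted p = 0.0715). NK cells and basophils are the same cells at both levels, yet passed only as subsets. The test shares its estimate of the spread over the types of a level. For NK cells it gave unadjusted p = 0.0268 among major types and 0.00237 among subsets by edgeR. The subset calls rest on that shared spread. These calls rest on all 4 mice: the subset count was 0 without vehicle mouse 1 or without vehicle mouse 2, 2 without BLZ945 mouse 1 (Mono2, pDC) and 3 without BLZ945 mouse 2 (Mono2, pDC, N2). The major count was 4 without vehicle mouse 1, 6 without vehicle mouse 2, 0 without BLZ945 mouse 1 and 2 without BLZ945 mouse 2. The folds moved too: without vehicle mouse 1 or 2, the log2 fold change of MonoDC was 7.506 or 1.612 (vehicle mouse 2 had 0 such cells), of N3 -0.5319 or -1.818 and of NK cells 1.337 or 2.573.

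**Figure D1:**
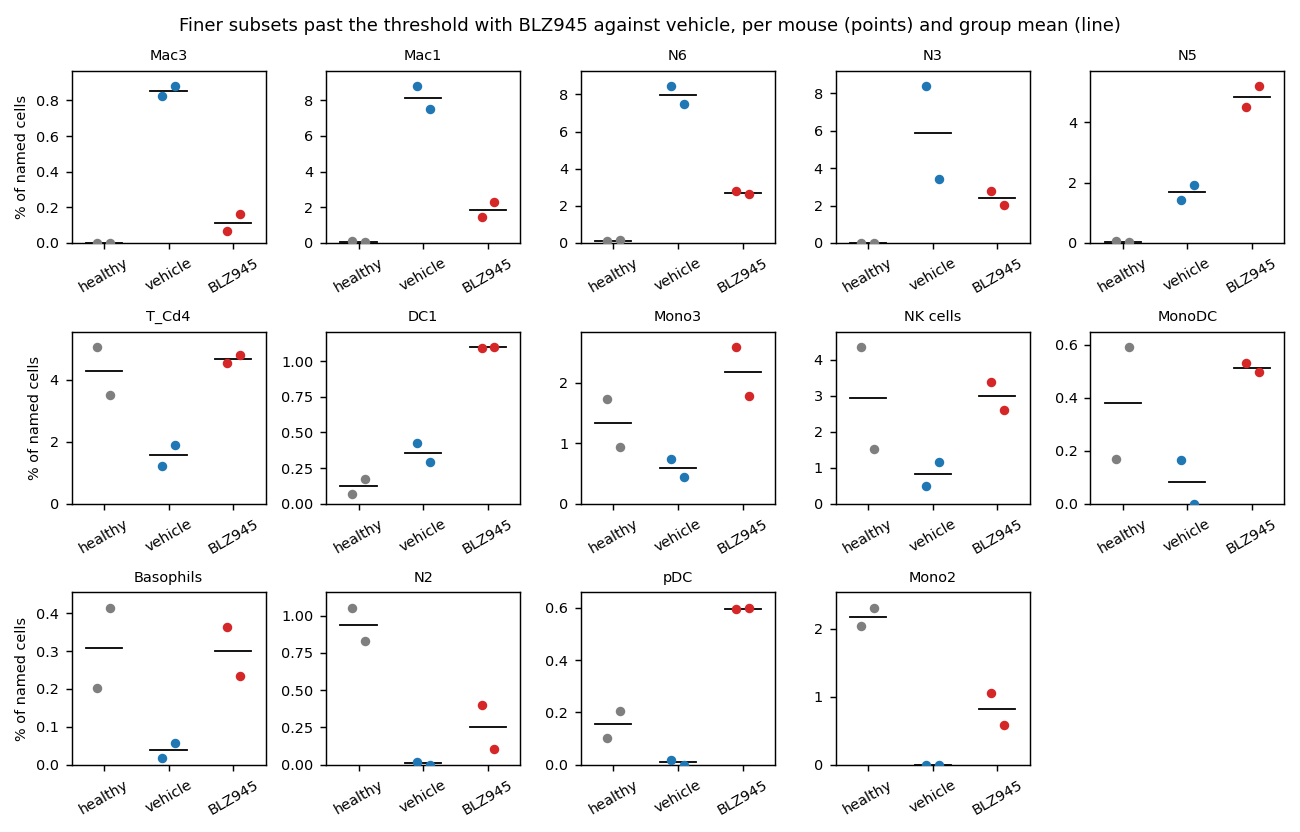
Percent of named cells in those of the authors' finer subsets that passed the threshold with BLZ945 against vehicle, 1 point per mouse.

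Within monocytes and macrophages, the C1q genes fell with BLZ945, and several genes of patrolling monocytes and of the interferon response rose. The 3 chains of the complement component C1q fell: C1qa (log2 fold change -1.72 ± 0.18, adjusted p = 0.000729), C1qb (log2 fold change -1.59 ± 0.17, adjusted p = 0.000729) and C1qc (log2 fold change -1.94 ± 0.20, adjusted p = 0.000538). Arginase 1, which consumes arginine, fell as well: Arg1 (log2 fold change -2.49 ± 0.24, adjusted p = 0.000499). Among patrolling monocyte genes, Cx3cr1 (log2 fold change 2.27 ± 0.27, adjusted p = 0.00109), the fractalkine receptor, Treml4 (log2 fold change 3.12 ± 0.40, adjusted p = 0.00293), Spn (log2 fold change 2.16 ± 0.24, adjusted p = 0.000846) and Cd300e (log2 fold change 3.76 ± 0.46, adjusted p = 0.00115) rose. In total 374 genes rose and 273 fell of 11709 tested. That count was 979 without BLZ945 mouse 2, 264 without vehicle mouse 1 and 356 without vehicle mouse 2.

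The lists fixed before the data were examined moved as follows in these cells. For the patrolling monocyte list, 13 of 20 tested members rose and 7 did not pass (adjusted p = 1.73e-14 by camera, adjusted p = 0.386 with an estimated correlation). Adjusted over the list alone, 14 rose. For the CSF1R-dependent macrophage list, 1 member (Cx3cr1) rose, 7 fell and 16 did not pass, with 2 and 12 adjusted over the list alone (adjusted p = 1.14e-05 by camera, adjusted p = 0.386 with an estimated correlation). Tmem37 (log2 fold change -1.94 ± 0.23, adjusted p = 0.00109) and Apoe (log2 fold change -1.50 ± 0.26, adjusted p = 0.00818), a lipid carrier, were among those that fell. The Apoe call ended with all 6 mice in the fit (adjusted p = 0.0783). Csf1r itself did not pass: Csf1r (log2 fold change 0.55 ± 0.20, adjusted p = 0.145), nor did the mannose receptor Mrc1 (log2 fold change -0.95 ± 0.30, adjusted p = 0.117), Trem2 (log2 fold change -0.66 ± 0.24, adjusted p = 0.147) or Spp1 (log2 fold change -0.09 ± 0.40, adjusted p = 0.935). Without BLZ945 mouse 2 the log2 fold change was 0.79 for Csf1r, -1.59 for Mrc1 and -1.18 for Trem2.

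For the type I interferon list, 12 of 27 tested members rose and 15 did not pass, with 22 rising adjusted over the list alone (adjusted p = 1.73e-14 by camera, adjusted p = 0.386 with an estimated correlation). Examples were Isg15 (log2 fold change 1.60 ± 0.24, adjusted p = 0.00308), a ubiquitin-like modifier, and Oasl2 (log2 fold change 1.93 ± 0.28, adjusted p = 0.00288). For the IFN-gamma list, 9 of 29 rose, or 15 adjusted over the list alone (adjusted p = 1.3e-09 by camera, adjusted p = 0.386 with an estimated correlation). Among them was Ciita (log2 fold change 2.13 ± 0.30, adjusted p = 0.00246), the master regulator of MHC class II. For MHC class I presentation, 5 of 19 rose, or 11 adjusted over the list alone (adjusted p = 1.29e-08 by camera, adjusted p = 0.386 with an estimated correlation), such as the immunoproteasome subunit Psmb9 (log2 fold change 1.34 ± 0.22, adjusted p = 0.00502). For proliferation, 1 of 30 rose and 3 fell, or 1 and 10 adjusted over the list alone (adjusted p = 3.2e-05 by camera, adjusted p = 0.386 with an estimated correlation). Among the falls was Birc5 (log2 fold change -1.64 ± 0.27, adjusted p = 0.00502). The calls of Cks2, the rise, and of Mki67 and Tubb5 ended with all 6 mice in the fit (adjusted p = 0.0947, 0.132 and 0.2899). For neutrophil granule genes, 6 of 18 fell (adjusted p = 0.000458 by camera, adjusted p = 0.386 with an estimated correlation), or 2 rose and 6 fell adjusted over the list alone, with Ngp (log2 fold change -4.72 ± 0.52, adjusted p = 0.00175) and Lcn2 (log2 fold change -1.91 ± 0.21, adjusted p = 0.000729) lower. Free RNA would give a median of 0.6245 of the fall over the 6 genes. It would give 2.946 for Ngp, 1.367 for Retnlg and 0.9016 for Lcn2, so these falls need not lie in the cells. For Wfdc21, Wfdc17 and Chil3 it would give a smaller part, 0.3475, 0.2277 and 0.1376. Median mitochondrial percent per cell was 2.20 and 2.52 with vehicle and 3.21 and 3.27 with BLZ945. The dissociation stress list was higher too (adjusted p = 8.18e-05 by camera, adjusted p = 0.438 with an estimated correlation).

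These type-level falls accompanied the smaller Mac1 share. Within Mac1 cells, C1qa (log2 fold change 0.10 ± 0.18, adjusted p = 0.879) and Arg1 (log2 fold change -0.66 ± 0.19, adjusted p = 0.136) did not pass. Mac1 cells did show rises of the lectin gene Siglecf (log2 fold change 2.19 ± 0.28, adjusted p = 0.000851), of Csf1, which encodes a CSF1R ligand (log2 fold change 1.51 ± 0.33, adjusted p = 0.039), and of B2m, the MHC class I light chain (log2 fold change 0.83 ± 0.17, adjusted p = 0.0257). Free RNA was computed after these values were seen, from shares per mouse that are each an upper limit. It would give 0.6153 of the Siglecf rise in Mac1, 1.144 of the Csf1 rise and 0.1952 of the B2m rise. The first 2 rises therefore need not lie in Mac1 cells. A difference between groups of such limits is not itself an upper limit, so the B2m value does not exclude free RNA. Mac1 had 74 calls, of which 33 were shared without vehicle mouse 1 and 26 without vehicle mouse 2. Platelet marker genes summed to 206.8 and 287.2 CPM in monocytes and macrophages with vehicle and to 21.1 and 47.0 with BLZ945.

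**Figure D2:**
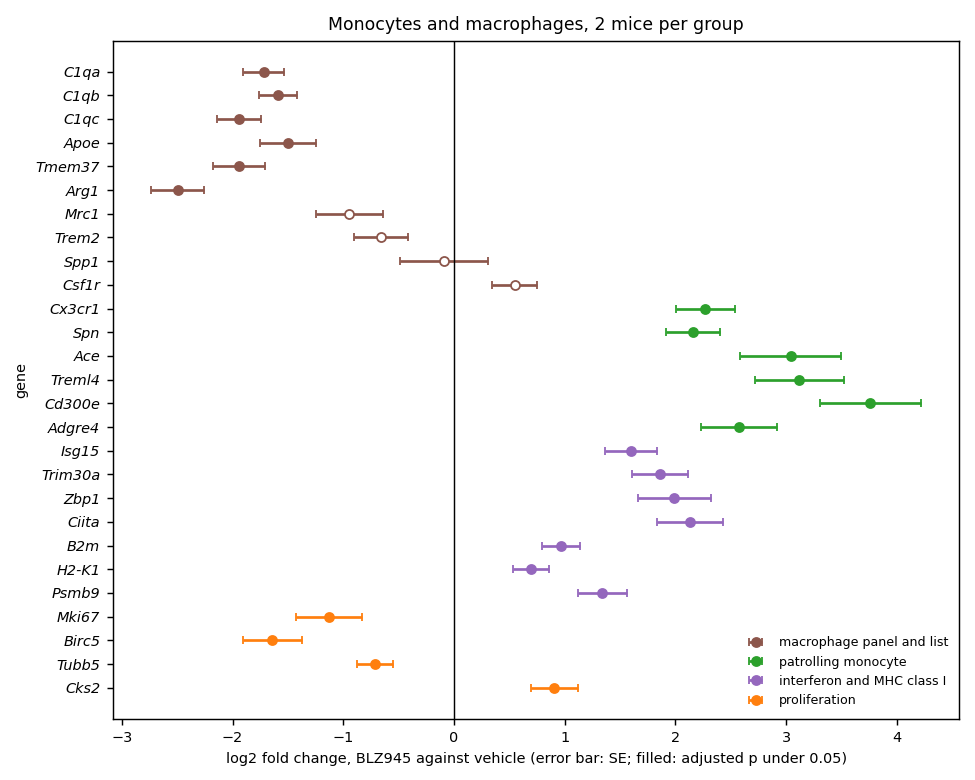
Log2 fold changes of genes in monocytes and macrophages with BLZ945 against vehicle, with standard errors.

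Neutrophils carried the largest number of changes: 1321 genes rose and 1287 fell of 16580 tested. Siglecf (log2 fold change 1.88 ± 0.17, adjusted p = 8.08e-08) (GRCm38 chromosome 7, 43351341 to 43359531) and Csf1 (log2 fold change 1.73 ± 0.16, adjusted p = 9.07e-08) (GRCm38 chromosome 3, 107741048 to 107760469) rose. The share of neutrophils with a Siglecf UMI was 2.28 ± 0.624% in healthy mice, 23.5 ± 3.10% with vehicle and 57.8 ± 7.72% with BLZ945. In T cells, the background, it was 1.24% and 2.61% with vehicle and BLZ945. Median depth was 2069 and 2278 UMIs per neutrophil and 2084 and 2292 per T cell. Thinned to 1000 UMIs per cell, the neutrophil share was 14.2% and 43.5% and the T-cell share 0.709% and 1.04%. For Csf1 the share was 24.7 ± 1.75% and 54.04 ± 5.11%, against 0.771% and 1.40% in B cells at median depths of 1320 and 1804 UMIs. Thinned to 1000 UMIs, it was 15.3% and 39.2%, against 0.577% and 0.875%.

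For the SiglecF-high neutrophil list, 18 of 26 tested members rose, 1 fell and 7 did not pass, with 20 and 2 adjusted over the list alone (adjusted p = 5.59e-15 by camera, adjusted p = 0.386 with an estimated correlation). Examples were Ccl4 (log2 fold change 1.86 ± 0.14, adjusted p = 1.04e-08), a chemokine, Ptgs2 (log2 fold change 1.92 ± 0.18, adjusted p = 3.71e-07), the inducible cyclooxygenase, Atf3 (log2 fold change 1.44 ± 0.14, adjusted p = 2.13e-07) and Vegfa (log2 fold change 1.04 ± 0.16, adjusted p = 0.000169). Xbp1 (log2 fold change 0.07 ± 0.15, adjusted p = 0.824) did not pass. For inflammatory cytokines, 8 of 22 rose and 2 fell, or 10 and 3 adjusted over the list alone (adjusted p = 5.03e-05 by camera, adjusted p = 0.499 with an estimated correlation). The rises included Il1a (log2 fold change 2.16 ± 0.14, adjusted p = 1.04e-09) and the interleukin 1 antagonist Il1rn (log2 fold change 1.68 ± 0.18, adjusted p = 1.2e-06). For hypoxia and glycolysis, 9 of 24 rose and 1 fell, or 12 and 2 adjusted over the list alone (adjusted p = 7.72e-07 by camera, adjusted p = 0.387 with an estimated correlation). Among the rises was Hk2 (log2 fold change 1.33 ± 0.14, adjusted p = 1.22e-06), a hexokinase. Members of the SiglecF-high list recur in other lists: Ccl4 and Ptgs2 in that of inflammatory cytokines, Vegfa in hypoxia and Atf3 in dissociation stress.

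Interferon genes rose in neutrophils and granule genes fell. For type I interferon, 21 of 25 tested members rose, also 21 adjusted over the list alone (adjusted p = 4.46e-15 by camera, adjusted p = 0.386 with an estimated correlation). Examples were Rtp4 (log2 fold change 3.10 ± 0.22, adjusted p = 1.7e-08) and Rsad2 (log2 fold change 3.01 ± 0.42, adjusted p = 0.00483), an antiviral enzyme. For IFN-gamma, 20 of 30 rose and 2 fell, also 20 and 2 adjusted over the list alone (adjusted p = 7.84e-11 by camera, adjusted p = 0.386 with an estimated correlation). Among the rises were Gbp2 (log2 fold change 2.91 ± 0.24, adjusted p = 7.33e-08), a guanylate-binding protein, and Cxcl10 (log2 fold change 2.52 ± 0.23, adjusted p = 1.18e-07). For granule genes, 2 of 19 rose and 12 fell, or 2 and 13 adjusted over the list alone (adjusted p = 6.42e-14 by camera, adjusted p = 0.386 with an estimated correlation). Chil3 (log2 fold change -5.42 ± 0.26, adjusted p = 5.33e-11), a chitinase-like protein, Lcn2 (log2 fold change -2.35 ± 0.17, adjusted p = 3.68e-09), Mmp8 (log2 fold change -2.04 ± 0.17, adjusted p = 2.83e-08) and Wfdc21 (log2 fold change -2.09 ± 0.18, adjusted p = 3.8e-08) fell, as did Fbp1 (log2 fold change -5.43 ± 0.26, adjusted p = 2.98e-11) and Bcl2l15 (log2 fold change -4.82 ± 0.23, adjusted p = 8.68e-12) outside the list. Epithelial or tumour-cell markers in neutrophils summed to 65.6 and 58.0 CPM with vehicle and 23.6 and 33.0 with BLZ945. The dissociation stress list was higher in neutrophils (adjusted p = 0.0103 by camera, adjusted p = 0.526 with an estimated correlation), except without vehicle mouse 2 (adjusted p = 0.0598).

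Within neutrophil subsets, Siglecf rose in N1 (log2 fold change 1.64 ± 0.27, adjusted p = 0.000285), N3 (log2 fold change 1.71 ± 0.31, adjusted p = 0.000416), N4 (log2 fold change 1.86 ± 0.16, adjusted p = 6.29e-07), N5 (log2 fold change 1.49 ± 0.31, adjusted p = 0.0349) and N6 (log2 fold change 1.47 ± 0.20, adjusted p = 0.000312). Csf1 rose in N1 (log2 fold change 1.49 ± 0.20, adjusted p = 3.25e-05), N3 (log2 fold change 2.15 ± 0.22, adjusted p = 1.46e-07), N4 (log2 fold change 1.45 ± 0.16, adjusted p = 6.87e-06) and N6 (log2 fold change 1.12 ± 0.20, adjusted p = 0.00377) and did not pass in N5 (log2 fold change 1.15 ± 0.27, adjusted p = 0.0645). Gbp2 rose in N1 (log2 fold change 3.43 ± 0.31, adjusted p = 5.46e-07) and N4 (log2 fold change 2.68 ± 0.28, adjusted p = 4.94e-06). Over 17 subsets of all types, 2716 gene calls were higher and 2478 lower, most of them in N4 (1075 and 977) and N1 (899 and 810).

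**Figure D3:**
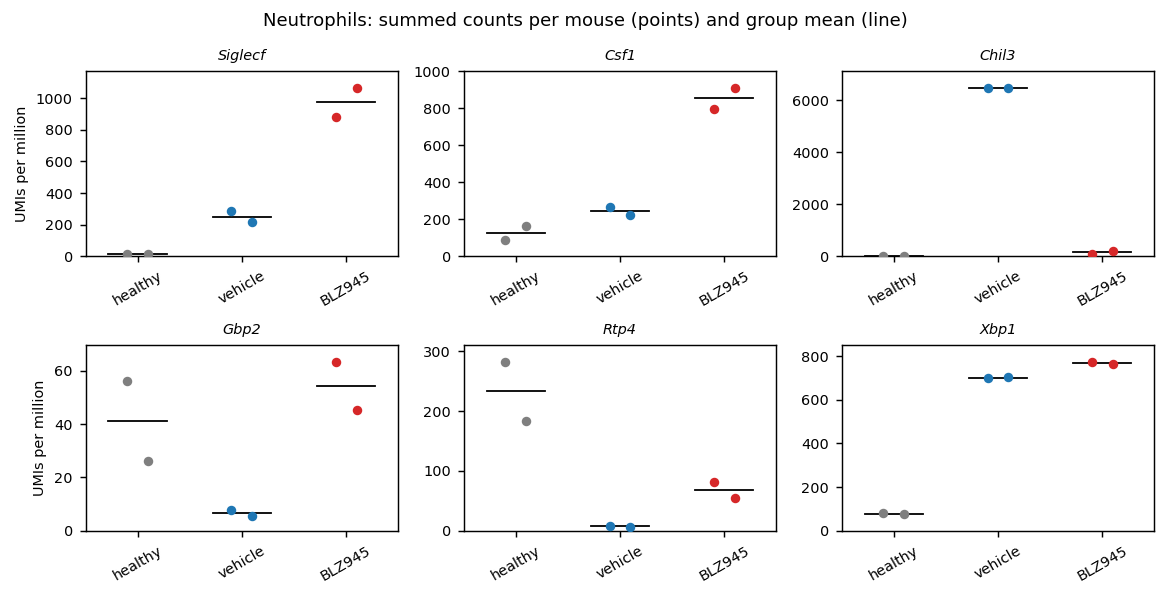
Genes in neutrophils, as CPM of each mouse.

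Dendritic cells showed 211 genes higher and 177 lower of 8042 tested. Transcripts of Cxcl9, a chemokine induced by IFN-gamma (GRCm38 chromosome 5, 92321347 to 92328079), numbered 58 with BLZ945 and 1 with vehicle, a ratio of 44.0 (95% counting interval 7.58 to 1766, adjusted p = 0.00239). They lay in 13 of 412 and 1 of 308 dendritic cells, mean shares of 3.474 ± 1.326% and 0.625 ± 0.884%, or 1.46% and 0.625% thinned to 1000 UMIs and 1.098% and 0.625% thinned to 500. In B cells 0 had a Cxcl9 UMI. Genes known from plasmacytoid cells rose while the pDC share rose: Irf8 (log2 fold change 2.52 ± 0.19, adjusted p = 1.1e-07), a transcription factor, Ly6d (log2 fold change 5.14 ± 0.35, adjusted p = 7.66e-08), Cox6a2 (log2 fold change 5.54 ± 0.50, adjusted p = 1.46e-06) and Bst2 (log2 fold change 2.07 ± 0.24, adjusted p = 3.25e-05). Gm21762 numbered 220 and 2 transcripts, a ratio of 83.4 (interval 22.8 to 692.7). Ch25h (log2 fold change -4.62 ± 0.69, adjusted p = 0.000764), Dpep2 (log2 fold change -3.03 ± 0.46, adjusted p = 0.000452) and Ddit4 (log2 fold change -2.89 ± 0.33, adjusted p = 5.07e-05) fell, as did the macrophage genes Mrc1 (log2 fold change -2.47 ± 0.31, adjusted p = 7.59e-05) and Apoe (log2 fold change -1.53 ± 0.30, adjusted p = 0.0054). The count of changed genes was 678 without vehicle mouse 1, 212 without BLZ945 mouse 1 and 258 without BLZ945 mouse 2.

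The make-up of dendritic cells also changed: from vehicle to BLZ945, DC2 went from 56.41% to 21.72% of them, DC1 from 11.29% to 25.72% and pDC from 0.219% to 14.05%, so changes over the type need not lie within its subsets. Markers of other cells moved in dendritic cells as well. Epithelial or tumour-cell markers summed to 175.7 and 441.6 CPM with vehicle and 85.8 and 76.58 with BLZ945, endothelial markers to 17.47 and 15.12 against 74.03 and 79.08, and platelet markers to 23.29 and 42.35 against 8.412 and 8.324. The dissociation stress list was higher (adjusted p = 0.0173 by camera, adjusted p = 0.438 with an estimated correlation), except without vehicle mouse 1 (adjusted p = 0.6802) or BLZ945 mouse 2 (adjusted p = 0.4551).

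Il12b (GRCm38 chromosome 11, 44400063 to 44414033), which encodes the shared subunit of IL12 and IL23, did not pass in dendritic cells: Il12b (log2 fold change 3.07 ± 1.66, adjusted p = 0.508). Its level was 58.9 and 166 CPM with BLZ945 and 0 and 45.4 with vehicle. Il12b UMIs were seen in 8 of 136 and 16 of 276 dendritic cells with BLZ945, and in 0 of 228 and 3 of 80 with vehicle, where 0 allows up to 1.32%. The mean shares were 5.84 ± 0.0603% and 1.88 ± 2.65%. In B cells 0 had an Il12b UMI in either group, allowing up to 0.214% and 0.579%. Median depth was 4142 and 4132 UMIs per dendritic cell and 1804 and 1320 per B cell. Thinned to 1000 UMIs, the dendritic shares were 4.20% and 1.25%, and to 500 UMIs 2.37% and 1.25%. In DC3, the share was 10.99 ± 5.06% with BLZ945 and 6.00 ± 8.49% with vehicle, or 9.04% and 4.00% thinned to 1000 UMIs. Thinned to 500 UMIs, the DC3 shares were 5.295% and 4.00%. Without vehicle mouse 2, which held every vehicle Il12b UMI, the log2 fold change of Il12b was 9.764, with no vehicle UMI left.

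Among the lists in dendritic cells, the mature programme had 8 of 31 tested members higher, 1 lower and 22 not passing, or 14 and 1 adjusted over the list alone (adjusted p = 9.12e-07 by camera, adjusted p = 0.386 with an estimated correlation). Cd83 (log2 fold change 1.16 ± 0.20, adjusted p = 0.0014) and Apol7c (log2 fold change 3.53 ± 0.50, adjusted p = 0.000249) rose (Apol7c not with DESeq2, adjusted p = 0.097), and Ccl17 (log2 fold change -1.11 ± 0.13, adjusted p = 1.92e-05) fell. Ccr7 (log2 fold change 0.46 ± 0.14, adjusted p = 0.0778), the lymph node homing receptor, did not pass. Its log2 fold change was 0.537 without vehicle mouse 1. For MHC class I, 7 of 19 rose, or 8 adjusted over the list alone (adjusted p = 1.6e-10 by camera, adjusted p = 0.386 with an estimated correlation). For IFN-gamma, 6 of 24 rose, or 9 adjusted over the list alone (adjusted p = 2.02e-07 by camera, adjusted p = 0.386 with an estimated correlation). MHC class II moved the other way: 3 of 13 fell, or 1 rose and 4 fell adjusted over the list alone (adjusted p = 0.00189 by camera, adjusted p = 0.386 with an estimated correlation). The falls included H2-Aa (log2 fold change -0.58 ± 0.09, adjusted p = 0.000527) and the protease Ctss (log2 fold change -0.93 ± 0.12, adjusted p = 9.69e-05). Cd40 (log2 fold change -0.52 ± 0.34, adjusted p = 0.476) and Flt3 (log2 fold change 0.26 ± 0.21, adjusted p = 0.596) did not pass.

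T cells showed 141 genes higher and 187 lower of 7420 tested. From vehicle to BLZ945, the CD4 subset went from 22.8% to 37.73% of T cells and the Ccr7-high CD8 subset from 50.74% to 31.4%. Changes over the type therefore need not lie within its subsets. Epithelial or tumour-cell markers in T cells summed to 25.31 and 37.63 CPM with vehicle and 11.65 and 18.02 with BLZ945. Genes that rose included Lgals1 (log2 fold change 1.53 ± 0.21, adjusted p = 7.83e-05), Ccl5 (log2 fold change 0.75 ± 0.15, adjusted p = 0.0033), Gzma (log2 fold change 2.21 ± 0.40, adjusted p = 0.00208), a granzyme, and Xcl1 (log2 fold change 1.301 ± 0.30, adjusted p = 0.0158), a chemokine for DC1. The calls of Ccl5 and Gzma ended without BLZ945 mouse 2 (adjusted p = 0.0723 and 0.063), and that of Xcl1 without BLZ945 mouse 1 (adjusted p = 0.558). The Gzma call also ended with all 6 mice in the fit (adjusted p = 0.716) and with DESeq2 (adjusted p = 0.165), and both Gzma and Xcl1 ended from 1500 UMIs per cell (adjusted p = 0.0858 each). For the cytotoxic list, 4 of 20 rose and 16 did not pass, or 5 rose adjusted over the list alone (adjusted p = 7.35e-05 by camera, adjusted p = 0.386 with an estimated correlation). For IFN-gamma, 4 of 26 rose, or 9 adjusted over the list alone (adjusted p = 4.68e-05 by camera, adjusted p = 0.386 with an estimated correlation), and for MHC class I, 3 of 19, also 3 adjusted over the list alone (adjusted p = 0.000166 by camera, adjusted p = 0.386 with an estimated correlation). The heat-shock gene Hsph1 (log2 fold change 3.50 ± 0.32, adjusted p = 4.42e-07) and Gm12840 (log2 fold change 2.40 ± 0.31, adjusted p = 6.24e-05) rose and Trnp1 (log2 fold change -3.98 ± 0.46, adjusted p = 9.46e-06) and Neb (log2 fold change -2.78 ± 0.41, adjusted p = 0.000182) fell. Gm12840 did not pass with DESeq2 (adjusted p = 0.0639). The dissociation stress list was higher (adjusted p = 0.012 by camera, adjusted p = 0.386 with an estimated correlation). Gzmb (log2 fold change 0.28 ± 0.37, adjusted p = 0.769), Prf1 (log2 fold change 0.40 ± 0.32, adjusted p = 0.566), Pdcd1 (log2 fold change -0.42 ± 0.55, adjusted p = 0.761), an inhibitory receptor, Ctla4 (log2 fold change -0.12 ± 0.26, adjusted p = 0.868) and Foxp3 (log2 fold change 1.72 ± 0.60, adjusted p = 0.113) did not pass. Without vehicle mouse 1 the log2 fold change was 1.351 for Gzmb, 1.255 for Prf1 and 1.917 for Foxp3. Without vehicle mouse 2 that of Gzmb was -0.335 and that of Prf1 -0.114, and without BLZ945 mouse 2 that of Foxp3 was 2.473. The number of changed genes was 591 without vehicle mouse 1, 94 without BLZ945 mouse 1 and 82 without BLZ945 mouse 2.

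Ifng (GRCm38 chromosome 10, 118441046 to 118445892), the gene of IFN-gamma, did not pass in T cells or NK cells: Ifng (log2 fold change -0.84 ± 0.55, adjusted p = 0.46) and, in NK cells, Ifng (log2 fold change 0.62 ± 0.35, adjusted p = 0.479). In T cells the log2 fold change was 1.41 without vehicle mouse 2, and without vehicle mouse 1 it was -1.69. NK cells with an Ifng UMI made up 14.3 ± 6.02% with vehicle and 24.6 ± 2.83% with BLZ945, at median depths of 1665 and 1894 UMIs. Thinned to 1000 UMIs the shares were 12.4% and 17.0%, and to 500 UMIs 6.20% and 13.9%. Among B cells, at median depths of 1320 and 1804 UMIs, 0 had an Ifng UMI, allowing up to 0.579% and 0.214%. T cells with an Ifng UMI made up 1.54 ± 0.127% and 2.22 ± 0.354%, or 1.20% and 1.65% thinned to 1000 UMIs. Thinned to 500 UMIs, the T-cell shares were 0.9988% and 1.01%.

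NK cells had 0 genes higher and 1 lower of 2832 tested by edgeR, 362 genes at an unadjusted p under 0.05, and 40 passed with DESeq2. The single gene, named after its values were seen, was Gm42031 (log2 fold change -2.85, adjusted p = 0.0363). The count was 249 without vehicle mouse 1, 108 without vehicle mouse 2, 0 without BLZ945 mouse 1 and 2 without BLZ945 mouse 2. The granzymes Gzma (log2 fold change 0.16 ± 0.18, adjusted p = 0.777) and Gzmb (log2 fold change -0.69 ± 0.29, adjusted p = 0.36), perforin Prf1 (log2 fold change 0.37 ± 0.24, adjusted p = 0.536) and the transcription factor Tbx21 (log2 fold change 1.38 ± 0.36, adjusted p = 0.219) did not pass. Without vehicle mouse 1, the log2 fold change was 0.372 for Gzma, 0.747 for Prf1 and 1.864 for Tbx21. That of Gzmb was -1.08 without vehicle mouse 2. In NK cells Xcl1 and Ccl5 each changed direction between the fits without vehicle mouse 1 or 2. The log2 fold changes were 3.936 or -1.236 for Xcl1 and -0.355 or 0.4153 for Ccl5. The dissociation stress list was higher (adjusted p = 0.00547 by camera, adjusted p = 0.452 with an estimated correlation), except without vehicle mouse 2 (adjusted p = 0.8928).

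B cells showed 126 genes higher and 155 lower of 7128 tested. Endothelial markers in B cells summed to 109.8 and 75.6 CPM with vehicle and 123.7 and 155.9 with BLZ945. Genes that rose included Cd83 (log2 fold change 1.63 ± 0.32, adjusted p = 0.0143), Il4i1 (log2 fold change 3.10 ± 0.56, adjusted p = 0.00978), Ly6a (log2 fold change 1.41 ± 0.27, adjusted p = 0.0124), Snrnp25 (log2 fold change 2.41 ± 0.40, adjusted p = 0.00662) and Ifi30 (log2 fold change 1.11 ± 0.20, adjusted p = 0.0111), a lysosomal thiol reductase. The chaperone gene Hspa1b numbered 176 and 2 transcripts, a ratio of 24.5 (95% counting interval 6.67 to 203.5), and the dissociation stress list was higher, with 7 of 21 members rising and 8 adjusted over the list alone (adjusted p = 1.08e-06 by camera, adjusted p = 0.386 with an estimated correlation). Fkbp5 (log2 fold change -3.13 ± 0.22, adjusted p = 3e-05), a co-chaperone of the glucocorticoid receptor, Gkap1 (log2 fold change -3.68 ± 0.69, adjusted p = 0.0113) and Lifr (log2 fold change -3.43 ± 0.47, adjusted p = 0.00202) fell. The number of changed genes was 804 and 537 without vehicle mouse 1 or 2, 131 and 109 without BLZ945 mouse 1 or 2, and 117 in cells with at least 1500 UMIs. In those cells the calls of Ifi30 (log2 fold change 0.4204, adjusted p = 0.396), Il4i1 (adjusted p = 0.0926), Ly6a (0.06), Snrnp25 (0.0632), Gkap1 and Hspa1b (0.0664 each) ended. Cd83 did not pass with DESeq2 (adjusted p = 0.115).

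**Figure D4:**
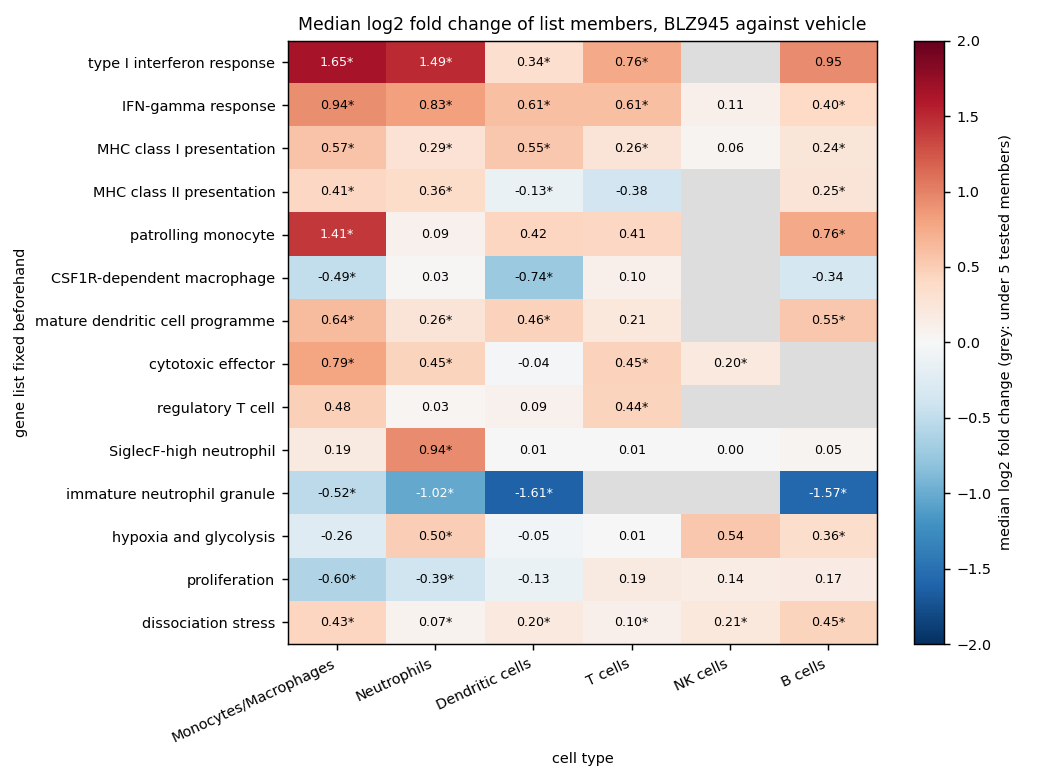
Median log2 fold change of selected gene lists in each tested major cell type, BLZ945 against vehicle. No list passed with an estimated correlation.

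With 2 mice in each group, a change that both mice of a group share for another reason cannot be separated from treatment. A change in 1 mouse alone can still carry much of the mean of its group. On simulated changes in monocytes and macrophages, drawn gene by gene with 1 common dispersion, 34.3% of 2-fold and 90.9% of 4-fold changes were recovered over 11360 genes.

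The comparison of vehicle-treated tumour-bearing mice with healthy mice showed a different myeloid compartment, with macrophage and neutrophil subsets that healthy lungs hardly held. Mac1 was 0.0804 ± 0.0302% of cells in healthy lungs (log2 fold change 6.62 ± 0.62, adjusted p = 0.000224). Mac2 and Mac3 counted 0 cells in healthy mice and were at least 23.9-fold and at least 17.9-fold higher with tumour (adjusted p = 0.000578 and 0.000686). The neutrophil subset N3, with 0 healthy cells, was at least 136.4-fold higher (adjusted p = 0.000578), and N4 (log2 fold change 5.53 ± 0.63, adjusted p = 0.000336) and N6 (log2 fold change 5.95 ± 0.58, adjusted p = 0.000224) rose. Among the subsets that fell, Mono2 was at least 64.3-fold lower (adjusted p = 0.000336). N1 fell from 64.7 ± 3.24% to 21.3 ± 2.03% (log2 fold change -1.60 ± 0.43, adjusted p = 0.0159), and CD4 T cells fell too (log2 fold change -1.45 ± 0.49, adjusted p = 0.0338). Without any 1 of these 4 mice, the calls of N1 and CD4 T cells ended.

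Of 28 subsets, 11 rose and 6 fell. Dendritic cells were higher as a major type (log2 fold change 2.69 ± 0.45, adjusted p = 0.0208), with DC2 (log2 fold change 3.66 ± 0.66, adjusted p = 0.00214) and DC3 (log2 fold change 3.69 ± 0.67, adjusted p = 0.00216), and pDC numbered 10 in healthy and 1 in vehicle mice, a ratio of 14.0 (95% counting interval 1.99 to 606.6, adjusted p = 0.0205). The pDC call ended without healthy mouse 2 or vehicle mouse 2. Of 8 major types, 1 rose and 1, basophils, fell (log2 fold change -3.06 ± 0.76, adjusted p = 0.0474). The basophil call ended without healthy mouse 2 (adjusted p = 0.162) or vehicle mouse 1 (adjusted p = 0.123). The number of major types past the threshold was 1 without vehicle mouse 1 and 5 without vehicle mouse 2.

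**Figure D5:**
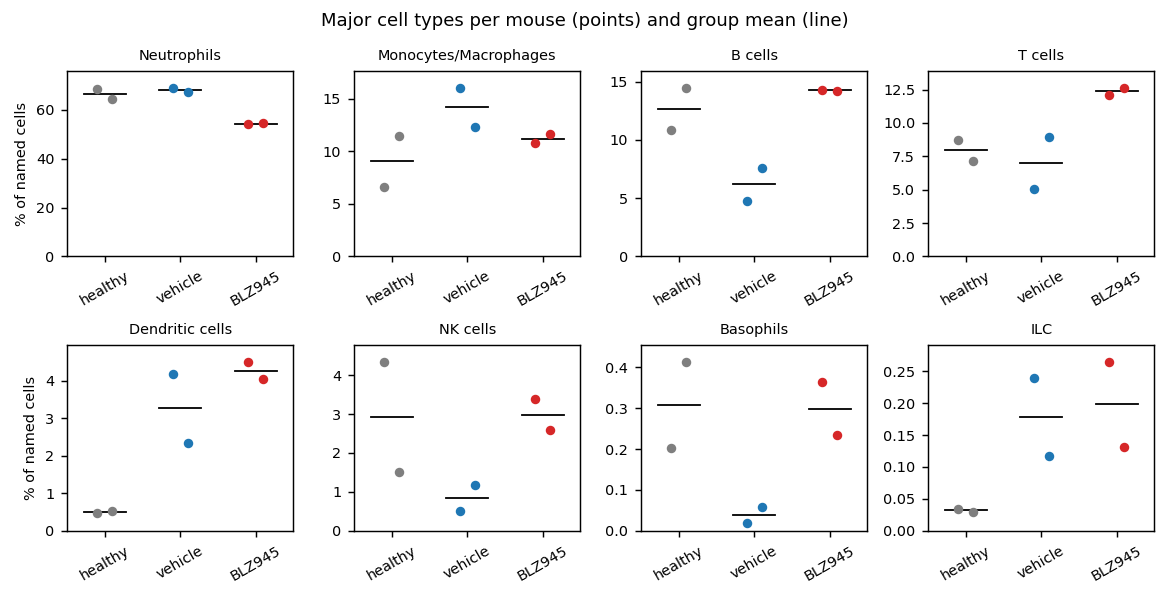
Percent of named cells in each major cell type, 1 point per mouse.

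In monocytes and macrophages, 1306 genes rose and 1562 fell of 10396 tested with tumour. Arg1 had 18087 transcripts with tumour and 0 in healthy mice, at least 1490-fold higher against a floor of 3 transcripts over the group (adjusted p = 3.7e-05). Complement genes C1qa (log2 fold change 5.11 ± 0.26, adjusted p = 3.7e-05), C1qb (log2 fold change 5.65 ± 0.43, adjusted p = 0.000186) and C1qc (log2 fold change 5.75 ± 0.25, adjusted p = 2.49e-05) rose, as did the elastase Mmp12 (log2 fold change 6.43 ± 0.40, adjusted p = 8.38e-05), Spp1 (log2 fold change 3.88 ± 0.52, adjusted p = 0.00159), which encodes osteopontin, Trem2 (log2 fold change 3.12 ± 0.29, adjusted p = 0.000345), a lipid receptor, and Gpnmb (log2 fold change 3.97 ± 0.42, adjusted p = 0.000625). Cx3cr1 (log2 fold change -2.85 ± 0.28, adjusted p = 0.000478), Ace (log2 fold change -4.52 ± 0.42, adjusted p = 0.000349) and Csf1r (log2 fold change -1.58 ± 0.26, adjusted p = 0.0038) fell. The immunosuppressive macrophage list had 11 of 19 members higher, 3 lower and 5 not passing, also 11 and 3 adjusted over the list alone (adjusted p = 0.000321 by camera, adjusted p = 0.54 with an estimated correlation). For hypoxia and glycolysis, 11 of 23 rose, or 13 adjusted over the list alone (adjusted p = 0.000121 by camera, adjusted p = 0.55 with an estimated correlation). For lipid and lysosome genes, 12 of 25 rose and 3 fell, or 13 and 3 adjusted over the list alone (adjusted p = 0.000764 by camera, adjusted p = 0.55 with an estimated correlation). An example of a rise was Cd63 (log2 fold change 4.13 ± 0.22, adjusted p = 4.46e-05). For the CSF1R-dependent list, 10 of 23 rose and 4 fell, or 12 and 4 adjusted over the list alone (adjusted p = 0.00212 by camera, adjusted p = 0.54 with an estimated correlation). Platelet markers in these cells summed to 7.434 and 16.12 CPM in healthy mice and 206.8 and 287.2 with vehicle.

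Patrolling monocyte and interferon genes were lower in these cells with tumour. For patrolling monocytes, 16 of 20 fell and 4 did not pass, also 16 adjusted over the list alone (adjusted p = 6.26e-10 by camera, adjusted p = 0.54 with an estimated correlation). For type I interferon, 19 of 25 fell, or 21 adjusted over the list alone (adjusted p = 6.26e-10 by camera, adjusted p = 0.54 with an estimated correlation). These included Irf7 (log2 fold change -3.33 ± 0.49, adjusted p = 0.00234), a transcription factor. For IFN-gamma, 13 of 24 fell, or 15 adjusted over the list alone (adjusted p = 0.000218 by camera, adjusted p = 0.54 with an estimated correlation). Among them was Ifi47 (log2 fold change -3.15 ± 0.28, adjusted p = 0.000293). For MHC class I, 10 of 19 fell, or 1 rose and 10 fell adjusted over the list alone (adjusted p = 0.00099 by camera, adjusted p = 0.54 with an estimated correlation). A fall was that of B2m (log2 fold change -1.97 ± 0.18, adjusted p = 0.000293). The number of changed genes was 1327 without vehicle mouse 1 and 1310 without vehicle mouse 2.

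In neutrophils, 4643 genes rose and 4489 fell of 15335 tested. Chil3 (log2 fold change 8.55 ± 0.29, adjusted p = 3.85e-10), Siglecf (log2 fold change 3.74 ± 0.23, adjusted p = 3.37e-08), Xbp1 (log2 fold change 2.89 ± 0.18, adjusted p = 4.39e-08), a transcription factor of the unfolded protein response, Ier3 (log2 fold change 3.60 ± 0.21, adjusted p = 2.42e-08) and the carbonic anhydrases Car2 (log2 fold change 8.08 ± 0.39, adjusted p = 4.48e-09) and Car4 (log2 fold change 7.86 ± 0.39, adjusted p = 5.24e-09) rose. Rsad2 (log2 fold change -5.08 ± 0.29, adjusted p = 2.1e-08) and Rtp4 (log2 fold change -5.24 ± 0.27, adjusted p = 6.6e-09) fell. For the SiglecF-high list, 18 of 26 members rose, 6 fell and 2 did not pass, or 19 and 6 adjusted over the list alone (adjusted p = 0.0048 by camera, adjusted p = 0.54 with an estimated correlation). That list was written from general knowledge of neutrophils in this tumour model, so its direction here is not independent evidence. For type I interferon, 1 of 25 rose and 21 fell, with the same counts adjusted over the list alone (adjusted p = 2.01e-08 by camera, adjusted p = 0.54 with an estimated correlation). For MHC class I, 2 of 19 rose and 10 fell, or 2 and 10 adjusted over the list alone (adjusted p = 0.0129 by camera, adjusted p = 0.54 with an estimated correlation). Epithelial or tumour-cell markers in neutrophils summed to 5.986 and 7.226 CPM in healthy mice and 65.64 and 57.99 with vehicle, and plasma cell markers to 94.89 and 82.07 against 741.4 and 729.8. The plasma cell markers include Xbp1, which rose in neutrophils, so that sum need not reflect plasma cells.

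In T cells, 484 genes rose and 615 fell of 6939 tested. The CD4 subset went from 53.36% of T cells in healthy mice to 22.8% with vehicle, and the Ccr7-high CD8 subset from 28.77% to 50.74%. Changes over T cells therefore need not lie within subsets. The naive and memory list had 7 of 14 members lower, also 7 adjusted over the list alone (adjusted p = 0.000432 by camera, adjusted p = 0.54 with an estimated correlation). These included S1pr1 (log2 fold change -1.52 ± 0.22, adjusted p = 3.17e-06), the receptor for lymph node exit, and Lef1 (log2 fold change -1.03 ± 0.21, adjusted p = 0.000528). In B cells, 471 rose and 597 fell of 6719. MHC class II had 6 of 13 members lower, or 7 adjusted over the list alone (adjusted p = 0.000321 by camera, adjusted p = 0.55 with an estimated correlation). Among them were H2-Ab1 (log2 fold change -1.35 ± 0.17, adjusted p = 3.43e-06) and the invariant chain Cd74 (log2 fold change -0.94 ± 0.15, adjusted p = 8.12e-05). Endothelial markers summed to 147.4 and 183.9 CPM in T cells of healthy mice and 74.34 and 98.79 with vehicle, and in B cells to 274.4 and 240.9 against 109.8 and 75.6. In NK cells, 92 rose and 77 fell of 1601. Ifng (log2 fold change 2.24 ± 0.62, adjusted p = 0.0241) rose. The Ifng call ended without healthy mouse 1, healthy mouse 2 or vehicle mouse 1 (adjusted p = 0.291, 0.0642 and 0.271), without a filter and with DESeq2. The number of changed genes was 572 and 538 in T cells without vehicle mouse 1 or 2, and 56 and 72 in NK cells without healthy mouse 1 or 2.

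Tumour and healthy mice also differed in sex, vehicle injection, library date, inDrops version and read length, and none of these can be separated from the tumour. Median mitochondrial percent per cell was 0.816 and 0.697 in healthy mice and 2.20 and 2.52 with vehicle. Xist, expressed from the inactive X, marked the female mice in every tested type (in neutrophils Xist (log2 fold change 5.78 ± 0.26, adjusted p = 2.41e-09)), and the Y-linked genes Ddx3y (log2 fold change -4.26 ± 0.24, adjusted p = 1.43e-08) and Eif2s3y (log2 fold change -5.59 ± 0.29, adjusted p = 7.04e-09) the male, healthy mice. Among the genes named by the rule were annotated non-coding RNA genes: Gm22758 was at least 173.3-fold higher in neutrophils and at least 151.5-fold higher in T cells, and Gm39214 at least 178-fold lower in monocytes and macrophages.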

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

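The tests of handling, of read length and library version, of other glucocorticoid-responsive genes and of free RNA for the interferon and MHC class I genes, as split by type, were chosen after the results were seen. The other 4 tests were set before. The free RNA test set before took all of these types together, 52 gene and type pairs with a median share of 0.082, and was split after the monocyte and macrophage values were seen.

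Many interferon and MHC class I genes were higher with BLZ945 in several cell types. No list passed with an estimated correlation, but with 4 mice that test passed no list of any kind. Free RNA in the suspension would give a median of 0.0191 of the observed rise over 27 called members in B, T and dendritic cells, which argues against it there. A changed mix of neutrophil subsets is argued against as the whole cause, since the rise within subsets was 1.31 times that of all neutrophils as a median over subsets, and 33 of 36 members in N1, 34 of 43 in N4 and 7 of 15 in N3 were called higher. In N5 0 of 10 and in N6 2 of 18 were called, and the ratio in N6 was 0.5455, so a part played by the mix stays open. In dendritic cells the mix stays open too, since the rise was 0.5069 (DC2) and 0.5742 (DC3) of that of the type, with 0 members called. So it does in T cells, with ratios of 0.6903 to 1.3 over 5 subsets and 1 member called. In monocytes and macrophages, free RNA (0.251 of the rise over 25 members) and a changed mix of subsets (the rise within subsets was 0.672 of that in all such cells) stay open. So does handling, since the lowest median mitochondrial percent of a BLZ945 mouse exceeded the highest of a vehicle mouse by 0.694, and BLZ945 treatment itself cannot be told apart from it in these 4 mice.

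Some genes had far fewer UMIs in healthy than in vehicle mice, or the reverse. By the definition used, under 2% of the other group's level, there were 40 such genes, and by a limit of 3 UMIs there were 5, seen in a median of 5 types. The 27 that were low in vehicle mice were seen in a median of 4 of the 5 tested types. No such median was computed for all genes at this level, so it does not by itself point to a cause. Of these, 59.26% were not protein coding, against 4.843% of all genes at this level, and with BLZ945 all 27 were nearer to the vehicle than to the healthy level. Read length and library version, which separate healthy from tumour libraries, may explain these 27, though the test was set after the values were seen. The 13 that were low in healthy mice were seen in a median of 3 types, and 30.77% were not protein coding. With BLZ945, 9 of the 13 were nearer to the vehicle than to the healthy level. Read length and library version stay open for these genes. Several of the 13 were macrophage genes such as Arg1, and Xist follows sex. Sex and tumour stay open as causes, untested.

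Fkbp5 was lower with BLZ945 in 5 of 6 tested types, with the level of both BLZ945 mice below both vehicle mice: Fkbp5 (log2 fold change -3.13 ± 0.22, adjusted p = 3e-05) in B cells, and log2 fold changes of -2.36 in dendritic cells (adjusted p = 8.7e-06), -2.57 in monocytes and macrophages (7.43e-05), -2.41 in neutrophils (9.19e-10) and -2.23 in T cells (1.22e-06). In NK cells Fkbp5 did not pass (log2 fold change -1.997, adjusted p = 0.0899), with both BLZ945 mice again lower. Free RNA would give a median of 0.0144 of the fall, which argues against it. The time of sampling stays open: 23.1% of 13 core clock genes passed in neutrophils, with an exact interval of 5.04% to 53.8%. By camera the clock list was lower in B cells (adjusted p = 0.00923) and T cells (adjusted p = 0.0213), but in neither with an estimated correlation (adjusted p = 0.3166 each). That percent met the bound set in advance against this explanation, but the interval reaches far past the bound, so it was not taken to exclude it. That use of the interval was added after the percent was seen. Per1, a clock gene, was placed in the list of glucocorticoid-responsive genes instead and was called lower in neutrophils. Counted with the clock genes, it would take the percent past that bound. A systemic glucocorticoid signal that differed between the groups is a candidate explanation, since a list of other responsive genes was lower by camera in 5 of 6 types, but no type passed with an estimated correlation (lowest adjusted p = 0.25).

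The median depth of 1 library was far above the others of its group in healthy mouse 1 (library 1, 2532 UMIs per named cell against 1453 to 1716) and in vehicle mouse 1 (library a, 2991 against 2048 to 2107). These were 2 of 27 measures tested, and chance alone picks about 1 in 20 groups. The BLZ945 change differed between the 6 types for Gbp2 (adjusted p of the interaction = 0.003684) and B2m (0.001576), and between dendritic cells and monocytes and macrophages for Csf1r (0.001576, difference 1.18), Mrc1 (9.979e-05, difference 1.54) and H2-Aa (8.032e-05, difference 0.79). Irf1 (0.543), Csf1 (0.32) and Apoe (0.908) did not pass that test. Cells that the authors marked Krt8-high numbered 14 with vehicle (9 and 5), 10 with BLZ945 (7 and 3) and 0 in healthy mice.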

How the results depend on the processing

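The test with a minimum of 1500 UMIs per cell was chosen after the data were seen; where a result moved, the cause was not tested. With RLE factors, 142 of 143 named genes of BLZ945 against vehicle and 95 of 95 of vehicle against healthy kept direction and side of the threshold. With DESeq2 these were 109 of the 123 that it gave a value for and 90 of 95, with all 6 mice 123 of 143 and 95 of 95, and without 1 mouse 115 to 122 of up to 143 and 86 to 92 of 95. The largest shift in the percent of calls that were higher was from 48.8 to 55.4, for vehicle against healthy without a filter.

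For BLZ945 against vehicle, calls with DESeq2 were 191 in dendritic cells (388), 40 in NK cells (1), 1694 in neutrophils (2608) and 180 in T cells (328), with the values reported above in parentheses. Over major types DESeq2 gave 1405 higher and 1360 lower (2173 and 2080), and in finer subsets 1688 and 1483 (2716 and 2478). For vehicle against healthy it gave 571 in B cells (1068) and 573 in T cells (1099). With all 6 mice, calls were 146 in dendritic cells, 222 in monocytes and macrophages (647), 1627 in neutrophils and 155 in T cells, and 1210 higher and 1169 lower over types. In finer subsets that fit covered 15 of 17. From at least 1500 UMIs per cell, calls were 117 (281) and 424 in B cells, and 0 in NK cells by edgeR, where 362 had an unadjusted p under 0.05 over all cells and DESeq2 gave 40. In NK cells there were 17 and 102 (169) calls without a filter, and 0 at a minimum count of 30. List calls were 0 and 0 with an estimated correlation, and 5 and 11 with fry (61 and 27).

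Major types past the threshold for BLZ945 against vehicle (0) were 2 each with TMM factors, without neutrophils, from 1500 UMIs and with all 6 mice. For vehicle against healthy (2) they were 0 with TMM factors, 4 without neutrophils, 0 with the largest library and 4 with all 6 mice. Finer subsets for BLZ945 against vehicle (14) were 9 with TMM factors, 4 without neutrophils and 8 with the largest library. For vehicle against healthy (17) they were 7 without neutrophils.

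Mouse numbers were taken as labels only, since the labels do not say whether same-numbered mice shared a day or batch. Deviations of same-numbered mice correlated at -0.0257 (T cells) to 0.111 (monocytes and macrophages), which does not exclude a shared batch. With the number as a replicate block, calls were 448 in B cells (281), 641 in dendritic cells (388) and 1261 in monocytes and macrophages (647). They were 10 in NK cells (1), 2928 in neutrophils (2608) and 167 in T cells (328), and 8 finer subsets passed. Under the block, Xcl1 in NK cells turned to 0.234 and the share of ILC to 0.154.

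Without 1 mouse, calls for BLZ945 against vehicle ranged from 109 to 804 in B cells, 212 to 678 in dendritic cells, 264 to 979 in monocytes and macrophages, 0 to 249 in NK cells, 1887 to 2279 in neutrophils and 82 to 591 in T cells. Over types this was 1720 to 2405 higher and 1468 to 2360 lower, and in finer subsets 2044 to 3775 and 1723 to 3330. For vehicle against healthy they ranged from 734 to 854 in B cells, 1310 to 3593 in monocytes and macrophages, 56 to 200 in NK cells, 6797 to 9298 in neutrophils and 538 to 1018 in T cells, over types 4781 to 7540 higher and 4726 to 7213 lower. Lists ranged from 59 to 69 and from 30 to 34, major types from 0 to 6 and from 1 to 5, and finer subsets from 0 to 3 and from 12 to 14.

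Values that turned direction had not passed in the fit of the 4 compared mice, apart from camera tests of the lists of cytotoxic genes in NK cells (limma, adjusted p = 0.955 without vehicle mouse 2, 0.0008205 with all mice compared, 0.4989 with an estimated correlation) and of alveolar macrophage genes in monocytes and macrophages (limma, adjusted p = 0.0137 without BLZ945 mouse 2, 0.04039 with all mice compared, 0.735 with an estimated correlation). Over the mice left out, the adjusted p of the first list ranged from 1.1e-07 to 0.955 and of the second from 6.47e-12 to 0.307. For BLZ945 against vehicle they were, without vehicle mouse 1, Spp1 in monocytes and macrophages (0.559), Xcl1 in NK cells (3.936) and the share of ILC (0.547). Without vehicle mouse 2 they were Cd274 in dendritic cells (0.0306), Ccl5 in NK cells (0.4153), Cxcr2 in neutrophils (-0.0589), Ifng (1.41), Gzmb (-0.335) and Prf1 (-0.114) in T cells, and the share of dendritic cells (-0.00297). Without BLZ945 mouse 1 they were Spp1 (0.234), Xcl1 (0.053) and Cxcr2 (-0.0522), and without BLZ945 mouse 2 Cd274 in monocytes and macrophages (-0.36), Ccl5 (0.17), Ctla4 in T cells (0.24) and ILC (0.507). Without a filter they were Ccl5 (0.215) and Xcl1 (0.152) in NK cells and Ctla4 (0.0145), at a minimum count of 30 Ccl5 (0.0128), from 1500 UMIs Xcl1 (0.803) and ILC (0.248), and with the largest library ILC (0.438). The share of dendritic cells turned with TMM factors (-0.318) and without neutrophils (-0.162). For vehicle against healthy they were Gzmb in NK cells (-0.332) and the share of T cells (0.171) without vehicle mouse 1, Cxcr2 in neutrophils (0.0565) and Ifng in T cells (-0.816) without vehicle mouse 2, Cxcr2 without a filter (0.046), and the share of neutrophils with TMM factors (-0.00178) or without healthy mouse 2 (-0.0075). The other ends of the ranges without 1 mouse, for BLZ945 against vehicle, were -0.268 (Cd274 in dendritic cells), 0.776 (Cd274 in monocytes and macrophages), -0.547 (Spp1), -1.24 (Xcl1), -0.355 (Ccl5), 0.274 (Cxcr2), -1.69 (Ifng in T cells), 1.35 (Gzmb), 1.26 (Prf1) and -0.474 (Ctla4), and 0.834 (dendritic cells) and -0.488 (ILC) for shares. For vehicle against healthy they were 0.671 (Gzmb), -0.32 (Cxcr2) and 2.27 (Ifng), and 0.0848 (neutrophils) and -0.655 (T cells) for shares.

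Depth limits shares of cells with a UMI. Thinned to 1000 and to 500 UMIs, with BLZ945, they were 4.2% and 2.37% for Il12b and 1.46% and 1.1% for Cxcl9 in dendritic cells, 43.5% and 30.04% for Siglecf and 39.2% and 26.7% for Csf1 in neutrophils. With vehicle, Siglecf had 14.2% and 9.19% and Csf1 15.3% and 9.15%.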

Other observations

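Of the tests named in this part, that of glucocorticoid-responsive genes was chosen after the result was seen, and that of clock genes before. With BLZ945, a compound aimed at CSF1R, neutrophils, the type with most cells, had more genes called than any other tested type. Siglecf and Csf1 rose in most neutrophil subsets (log2 fold change 1.86 ± 0.16, adjusted p = 6.29e-07 for Siglecf and log2 fold change 1.45 ± 0.16, adjusted p = 6.87e-06 for Csf1 in N4), with both BLZ945 mice above both vehicle mice, while granule genes such as Lcn2 fell.

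The Mono2 subset and patrolling monocyte genes moved together, though which cells carry these genes was not tested. Mono2 was not seen with vehicle and was seen in healthy and BLZ945 mice, and the patrolling monocyte list was lower with tumour and higher with BLZ945 by camera, but not with an estimated correlation (adjusted p = 0.5399 and 0.3862). Both comparisons share the vehicle mice, so an unusual level in these 2 mice would give the same picture.

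Fkbp5 and some other glucocorticoid-responsive genes were lower with BLZ945, though the list passed in no type with an estimated correlation (lowest adjusted p = 0.25). In neutrophils 13 of 19 members of the list were called lower and 1, Cxcr4, higher, while 7 of 11 were lower in T cells, 7 of 15 in dendritic cells, 6 of 18 in monocytes and macrophages, 5 of 11 in B cells and 0 of 7 in NK cells. The level of Fkbp5 in B cells was 15.0 CPM in healthy mice, 297 with vehicle and 36.9 with BLZ945. Against healthy mice Fkbp5 was higher with vehicle in 5 of 5 tested types, but the list passed by camera only in B cells (adjusted p = 0.02132), and not there with an estimated correlation (adjusted p = 0.4183). Corticosterone was not measured in the files used here, and the 23.1% of clock genes past the threshold leave the time of sampling open as a possible explanation.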
